A study of Mus musculus with 6 samples.

How the data were processed

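Small RNA was sequenced in 6 libraries from skeletal muscle of male C57BL6 mice aged 16 weeks, 3 libraries after a sham operation (Sham) and 3 after transverse aortic constriction (TAC), a narrowing of the aortic arch that overloads the left ventricle and leads to hypertrophy and heart failure. The labels put the harvest at 8 weeks of treatment in each sample's record and at a range of weeks in the protocol, and do not say which muscle was taken. Per the labels' protocols, total RNA was extracted with a column kit that retains small RNA and made into libraries with the QIAseq miRNA kit, which tags each molecule with a unique molecular identifier (UMI) before amplification. Counting UMIs in place of reads removes most amplification duplicates. Ligation of the adapters still favours some sequences, so levels of different miRNAs within a library are not strictly comparable, while a given miRNA can be compared between libraries.

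The deposited workbook holds raw counts per library, as UMIs and as reads, for mature miRNAs and piRNAs, tRNAs, mRNA fragments, other RNAs and mappable sequences without annotation, together with read counts per category, per the file headers. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting rules and the filters on reads are not given in the sources used here. Each listed feature reached at least 10 UMIs in some library, and the listed miRNAs held a mean of 99.97% (Sham) and 99.98% (TAC) of the miRNA reads. Reads per UMI averaged 1.09 for miRNAs. Column names were matched to samples through the sample descriptions. All 6 columns were used. In the numbering of the columns all TAC libraries come before all Sham libraries, with a gap in the numbers between them. What the numbers mark is not given, so any effect of that order cannot be told apart from the groups.

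Total reads were 5146811, 3406425 and 1695043 in Sham 1, 2 and 3, and 3991766, 2966043 and 3182901 in TAC 1, 2 and 3. The miRNA UMIs numbered 3440232, 2360496 and 1179365 in Sham and 2874724, 2145221 and 2294503 in TAC. Mean ± SD values are over n = 3 libraries per group. Intervals and floors cover counting error only.

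UMI counts were tested per RNA class with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, and the two-sided quasi-likelihood F test of TAC against Sham. Adjusted p-values are Benjamini-Hochberg values within the class, with a threshold of 0.05. Unless another tool is named, every adjusted p for a miRNA or other feature comes from this edgeR test. The standard error (SE) of a log2 fold change was taken from the fold change and its F statistic. CPM values are UMIs per 1000000 UMIs of the RNA class after TMM scaling. Of 20 miRNA lists fixed beforehand, the 17 with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. An estimated correlation and fry were run beside it. Shares of reads were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1.

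The design, the lists, the alternatives and the naming rule were set before the data were examined. The rule names all tested muscle-enriched miRNAs, up to 10 miRNAs with the smallest p among those past the threshold in each direction, up to 4 members of each list past the threshold, up to 3 features per direction in each other class, and the 5 most abundant miRNAs. Alternatives covered the scaling (RLE, upper quartile, library size only, library sizes over all classes), the filter, the tool (DESeq2 1.42.0 and limma-voom), reads in place of UMIs, a threshold of 0.1, the replicate number as a block, and leaving out each library in turn. Leaving out both libraries numbered 3, and a Dlk1-Dio3 list drawn by position, were added after seeing the data. Marker mRNAs of other organs, and the form of the tests on them, were also chosen after the values were seen.

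The labels give both groups replicate numbers from 1 to 3 without saying what they mark. Deviations from the group means of the log2 CPM correlated between same-numbered libraries, across miRNAs, with r = 0.33, 0.31 and 0.59 for numbers 1, 2 and 3. By a criterion of r above 0.1 in every pair the numbers were read as pairing the libraries, and values with the replicate block are given where they change a call. The pairing is not unique, since Sham 2 correlated more with TAC 1 (r = 0.39) than with TAC 2 and Sham 1 more with TAC 2 (r = 0.34) than with TAC 1. These correlations are across miRNAs, which are not independent replicates. Deviations from a group mean cancel out within the group, so the agreement of the libraries numbered 3 also raises the correlations among numbers 1 and 2. The criterion therefore says little on numbers 1 and 2, and values with the replicate block rest on an uncertain pairing. Libraries of 1 group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 58.3 between any 2 libraries of the same group. The labels do not say whether each library came from its own mouse, so the p-values measure the spread between these libraries.

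The steps were tested on simulated counts with the means, dispersions and library sizes of these libraries, in 20 simulations each. All members of the Dlk1-Dio3 list were set to fall 2-fold, so its call shows recovery only. Besides the list, 60 miRNAs were changed, in a comparison of 312 miRNAs. Of those changes 40.8% of 2-fold and 93.8% of 4-fold ones were recovered, and 4.31% of calls were false. The list was called in 20 simulations, with a mean of 0.15 other lists called. Counts were drawn independently for each miRNA, so correlation between miRNAs was not simulated, and the number of other lists called may be too low for these libraries. With 200 of 1140 unannotated sequences changed, 30.6% of 2-fold and 93.8% of 4-fold changes were recovered and 3.01% of calls were false.

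Positions and gene overlaps come from GENCODE release M21, the same build as the deposited counts. A hairpin gene was found by name for 388 of 392 mature miRNAs, and 357 had 1 hairpin. Start positions of the unannotated sequences count from 0 in the deposited table, as shown by 34 of 34 exact hairpin matches, and are given here counted from 1. Near-identical miRNAs (miR-133a, miR-133b and miR-133c, miR-486a and miR-486b) and copies of tRNA genes can share reads, so the split between them is uncertain. Overlapping genes on either strand share the same limit, since the use of strand in counting is not given in the sources used here. Among these is the hairpin of miR-1b, which lies opposite a hairpin of miR-1a on chromosome 18.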

Results

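Small RNA libraries from skeletal muscle, 3 from Sham and 3 from TAC mice, were compared to ask which miRNAs differ in muscle during heart failure after aortic constriction. The series title places the question in insulin resistance and a muscle-specific miRNA. Libraries held between 1179365 (Sham 3) and 3440232 (Sham 1) miRNA UMIs. The muscle miRNA miR-1a-3p made up 46.1% ± 4.29 of miRNA UMIs in Sham and 46.0% ± 3.71 in TAC (SD, n = 3). It was followed by miR-133a-3p, with 10.9% ± 1.53 in Sham and 14.04% ± 2.91 in TAC (exact permutation p = 0.3). Next came miR-26a-5p (3.25% and 3.91%), miR-126a-3p (3.17% and 2.75%) and miR-378a-3p (2.89% and 2.75%), given as Sham and TAC means.

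Of 322 tested miRNAs, 71 passed the threshold, 20 of them higher and 51 lower in TAC. Most of the miRNAs that fell belonged to the imprinted Dlk1-Dio3 cluster on chromosome 12. Those that rose included the 3 guide strands of the miR-29 family and miR-122-5p, the main miRNA of hepatocytes. DESeq2 called 73 miRNAs. The groups did not overlap for 130 miRNAs (40.4%), where chance gives 10%. With library sizes in place of TMM factors the median log2 fold change shifted by -0.28 and 78 miRNAs passed, 10 higher and 68 lower, so the balance of higher and lower calls depended on the scaling. With the replicate block 111 miRNAs passed, including all 71. Without Sham 1, Sham 2, TAC 1 or TAC 2 the count was 17, 29, 32 or 24, and without both libraries numbered 3 it was 129.

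Among the 14 tested muscle-enriched miRNAs (myomiRs), 2 fell and 12 did not pass, with the same 2 past the threshold when adjusted over the list alone. The main measurement for the question of the series is miR-133b-3p, a myomiR encoded at chromosome 1, 20682769 to 20682887, plus strand, GRCm38. It had 2555 ± 570.3 CPM in Sham and 4445 ± 853 CPM in TAC (SD, n = 3), a log2 fold change of 0.80 (SE 0.25) with an adjusted p of 0.0527 by edgeR. All 3 TAC libraries lay above all 3 Sham libraries. The adjusted p was 0.00684 with the replicate block, 0.0485 with RLE factors, 0.0349 with upper-quartile factors, 0.0319 by DESeq2, 0.0411 without TAC 3, and 0.162 with library sizes only, and ranged from 0.00648 to 0.162 over all alternatives. The near-identical and more abundant miR-133a-3p moved the same way, from 99460 ± 20840 to 154200 ± 27300 CPM (log2 fold change 0.63, SE 0.21). Since both can share reads, the rise of miR-133b-3p is not shown to be its own. The neighbour of miR-133b-3p, miR-206-3p, enriched in slow and regenerating muscle, lies at 20679010 to 20679082 in the same annotated noncoding gene, Gm28653. It fell from 12410 ± 9502 to 2403 ± 1140 CPM, a log2 fold change of -2.37 (SE 0.62, adjusted p = 0.0342). That call was lost without any 1 library other than Sham 2, with adjusted p-values from 0.0651 to 0.109, and the log2 fold change without Sham 3 was -1.51.

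The slow-fibre myomiR miR-208b-3p, which lies within the slow myosin gene Myh7 (chromosome 14, 54975700 to 54975776, minus strand), was nearly lost in TAC. It had 247 UMIs over the Sham libraries and 2 over the TAC libraries, a scaled ratio of 109 with a 95% counting interval from 29.8 to 902 (adjusted p = 0.00769). Both TAC UMIs were in TAC 3. The log2 fold change, -6.65 (SE 1.04), was -9.45 without TAC 3 (adjusted p = 0.0174), which leaves 0 UMIs in TAC, and ranged from -9.45 to -6.04 over all alternatives, each past the threshold. Its partner in the slow-fibre list, miR-499-5p in Myh7b, had 200 UMIs in Sham and 15 in TAC, all 15 in TAC 3. The log2 fold change of miR-499-5p was -3.30 (SE 1.12), with an adjusted p of 0.0711 and of 0.0264 with the replicate block. Over all alternatives it ranged from -9.18 to -2.55, with adjusted p-values from 0.00652 to 0.272, and without TAC 3, which leaves 0 UMIs in TAC, the adjusted p was 0.0140. Of these 2 slow-fibre miRNAs 1 passed over all miRNAs and 2 when adjusted over the list alone. Fragments of Myh2, the myosin of fast oxidative fibres, did not pass in its tested transcript (log2 fold change -1.002, adjusted p = 0.498). Relative to 1000000 miRNA UMIs, its fragments were lower in every TAC library than in any Sham library (17.9 ± 10.5 in Sham, 5.71 ± 2.24 in TAC, SD, n = 3, exact permutation p = 0.1, the smallest possible). Reads of mRNA as a whole were also a lower share of all reads in every TAC library (0.493% ± 0.0883 in Sham, 0.346% ± 0.0441 in TAC, exact permutation p = 0.1, adjusted 0.24). Among all mRNA fragment UMIs, Myh2 made up 0.331% ± 0.163 in Sham and 0.162% ± 0.051 in TAC (exact permutation p = 0.1). The remaining myomiRs did not pass. The log2 fold changes were 0.63 for miR-133a-3p (adjusted p = 0.0697, and 0.00926 with the replicate block), 0.27 for miR-1a-3p, 0.35 for miR-1b-5p, 0.85 for miR-1a-1-5p, 0.24 for miR-1a-2-5p and 0.30 for miR-133a-5p. They were -0.27 and -0.25 for miR-486a-3p and miR-486a-5p, and 0.24 and -0.14 for miR-486b-3p and miR-486b-5p. The signs for miR-1a-3p, miR-1a-2-5p and miR-486b-3p turned with library sizes only. Over all alternatives miR-1a-1-5p ranged from 0.528 to 1.51 and passed in none. As a set the myomiRs had a median log2 fold change of 0.24 and a mean of -0.66, and camera did not call them (adjusted p = 0.891, upward).

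**Figure D1:**
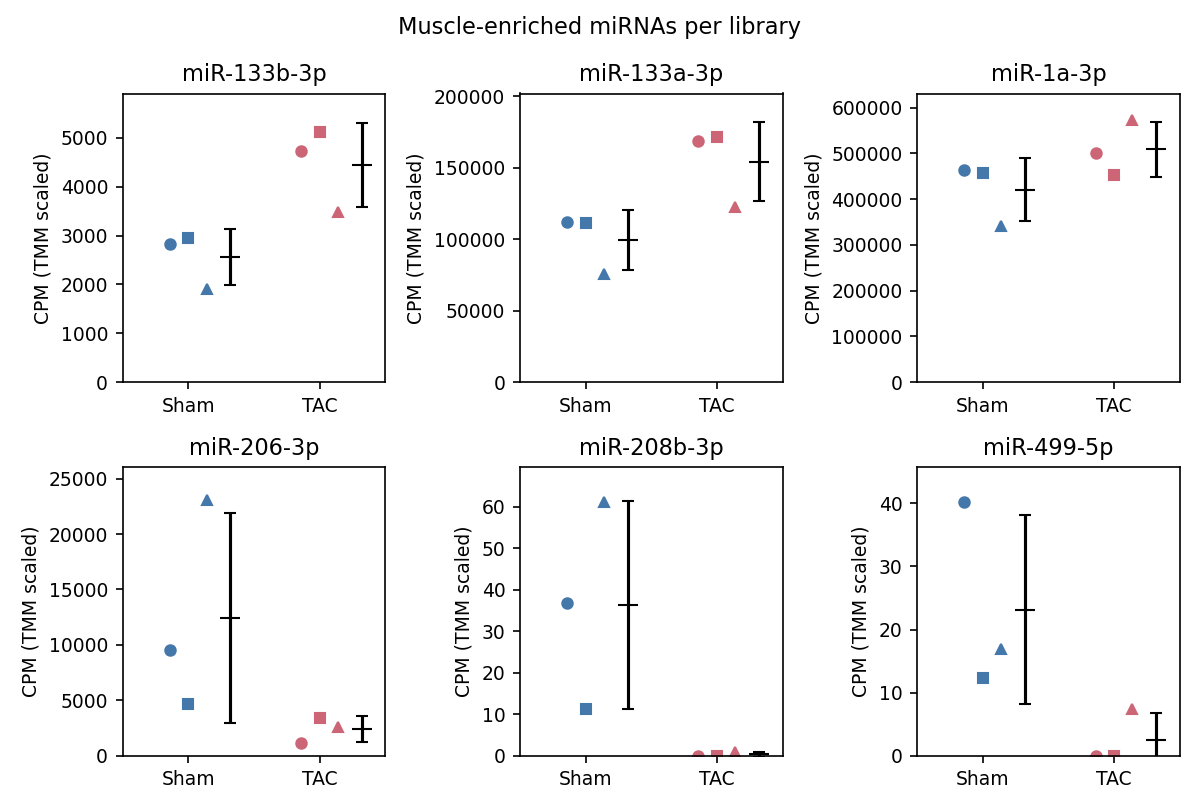
Scaled UMIs per 1000000 miRNA UMIs (CPM) of 6 muscle-enriched miRNAs in each library, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean and SD (cut at 0, n = 3). For miR-133b-3p the TAC mean of 4445 lay above the Sham mean of 2555, and for miR-208b-3p the TAC libraries together held 2 UMIs.

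In the Dlk1-Dio3 cluster, a maternally expressed array of miRNAs between the genes Dlk1 and Dio3 (chromosome 12, 109452823 to 110281097), 27 of 31 tested list members fell, 0 rose and 4 did not pass. Adjusted over the list alone, 29 fell. The median log2 fold change was -1.69 and all 31 members were below 0. Camera called the list (adjusted p = 7.7e-17, and adjusted p = 0.0222 with an estimated correlation), as did fry (adjusted p = 0.000502). With the preset correlation, every other split of the libraries also called at least 1 list. The most abundant member in Sham, miR-434-3p (109594506 to 109594599), fell from 912.5 ± 35.9 to 216 ± 75.3 CPM, a log2 fold change of -2.08 (SE 0.29). Others were miR-299a-5p (-2.34, SE 0.29), miR-382-5p (-1.81, SE 0.24) and miR-369-5p (-1.69, SE 0.24), each with an adjusted p of 0.00693. The list summed to 3849 ± 137 CPM in Sham and 1298 ± 107 CPM in TAC. Drawn by position, 33 of 40 tested miRNAs of the region fell and all 40 were below 0. The region also held 9 of the 10 miRNAs with the smallest p among those that fell, the others being miR-493-5p (-2.80), miR-127-5p (-2.33), miR-409-5p (-2.77), miR-323-3p (-2.87) and miR-337-5p (-2.53). The number of list members that fell was 8, 15, 15 and 12 without Sham 1, Sham 2, TAC 1 and TAC 2.

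**Figure D2:**
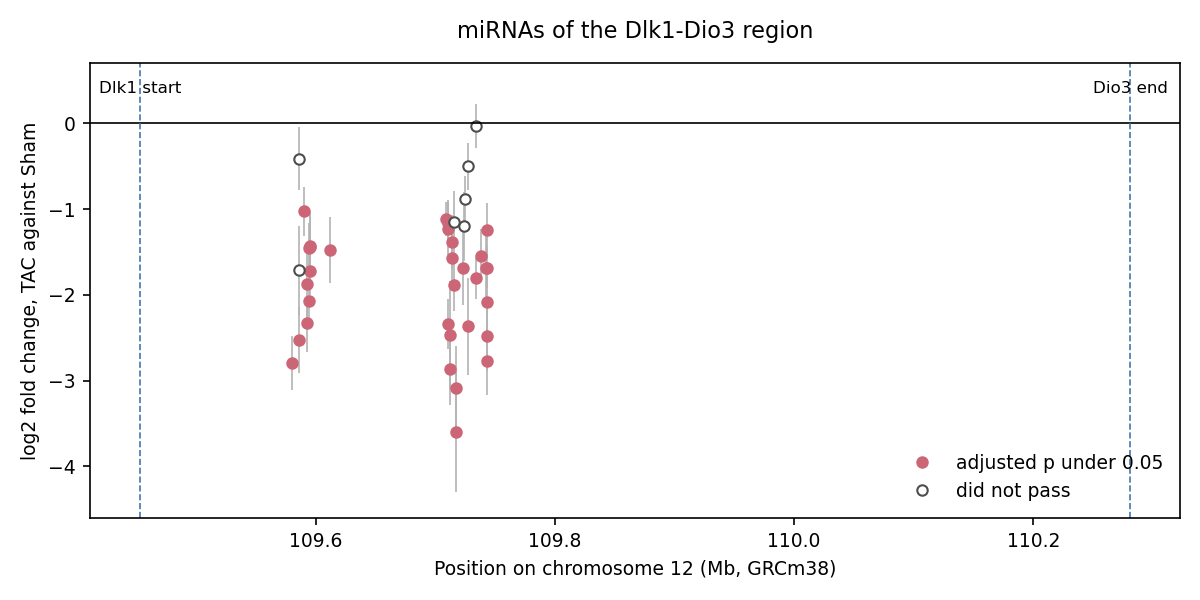
Log2 fold change of TAC against Sham with its SE for each tested miRNA with 1 hairpin in the Dlk1-Dio3 region, against the hairpin start on chromosome 12 (GRCm38, Mb). Filled points have an adjusted p under 0.05, open points did not pass, and dashed lines mark the start of Dlk1 at 109452823 and the end of Dio3 at 110281097.

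The miR-29 family, which targets collagens and components of insulin signalling, rose as a whole, with 3 of 3 members past the threshold, also when adjusted over the list alone. From Sham to TAC, miR-29b-3p went from 178 ± 29.4 to 727 ± 242 CPM (log2 fold change 2.02, SE 0.31, adjusted p = 0.00726). The more abundant miR-29c-3p went from 1709 ± 448 to 5178 ± 2008 CPM (1.60, SE 0.35) and miR-29a-3p from 8288 ± 855 to 12870 ± 1138 CPM (0.63, SE 0.17, adjusted p = 0.0338). Camera called the family (adjusted p = 0.0443), with adjusted p = 0.95 with an estimated correlation, and with 0.0574, 0.107 and 0.0768 without Sham 2, Sham 3 and TAC 2. The call of miR-29a-3p was lost with library sizes only (log2 fold change 0.36, adjusted p = 0.187), and calls of miR-29c-3p and miR-29a-3p were lost without Sham 1, Sham 2, TAC 1 or TAC 2 (adjusted p from 0.0507 to 0.12).

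Of 23 tested miRNAs tied to insulin signalling and glucose uptake, 3 rose, 1 fell and 19 did not pass, with the same numbers adjusted over the list alone. The members of these lists given here as single values outside the miR-29 family, and those of the miR-200 family, fall outside the naming rule and were chosen after their values were seen. Those that rose were the 3 miR-29 members, and miR-15b-5p fell (log2 fold change -0.90, SE 0.22). Camera gave an adjusted p of 0.0955 for this list, which was not past the threshold, and 0.0347 without TAC 3. Of 14 muscle atrophy miRNAs, miR-29b-3p rose and 3 fell: miR-532-5p (-0.94), miR-31-5p (-1.68) and miR-206-3p. The counts were the same adjusted over the list alone, camera did not call the list (adjusted p = 0.827) and fry did, downward (adjusted p = 0.0346). Of 10 TGF-beta and fibrosis miRNAs 3 rose, again the miR-29 members, and 3 when adjusted over the list alone (camera adjusted p = 0.291, and 0.0288 without TAC 3). In the miR-30 family 1 of 5 rose, miR-30a-5p (0.94), and in the miR-15/16 family 1 of 6 fell, miR-15b-5p. Both counts held adjusted over the list alone, and neither list was called (adjusted p = 0.401 and 0.713).

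Markers of other cell types mostly did not pass. No member passed in 10 lists with 52 tested miRNAs in edgeR, or in DESeq2, and 2 had an unadjusted p under 0.05. These lists were the let-7 family (9 tested), immune (9), erythroid (2), endothelial (2), smooth muscle and pericyte (4), fibroblast (5) and neural (3) markers, the miR-17-92 and miR-106b-25 clusters (8), hypoxia and p53 miRNAs (3) and the miR-23-27-24 clusters (7). None had a member past the threshold adjusted over the list alone. Among 7 epithelial and liver markers, miR-122-5p rose and 3 members of the epithelial miR-200 family fell. The same 4 passed adjusted over the list alone, and camera did not call this mixed list (adjusted p = 0.891, median log2 fold change 0.22, mean -0.43).

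**Figure D3:**
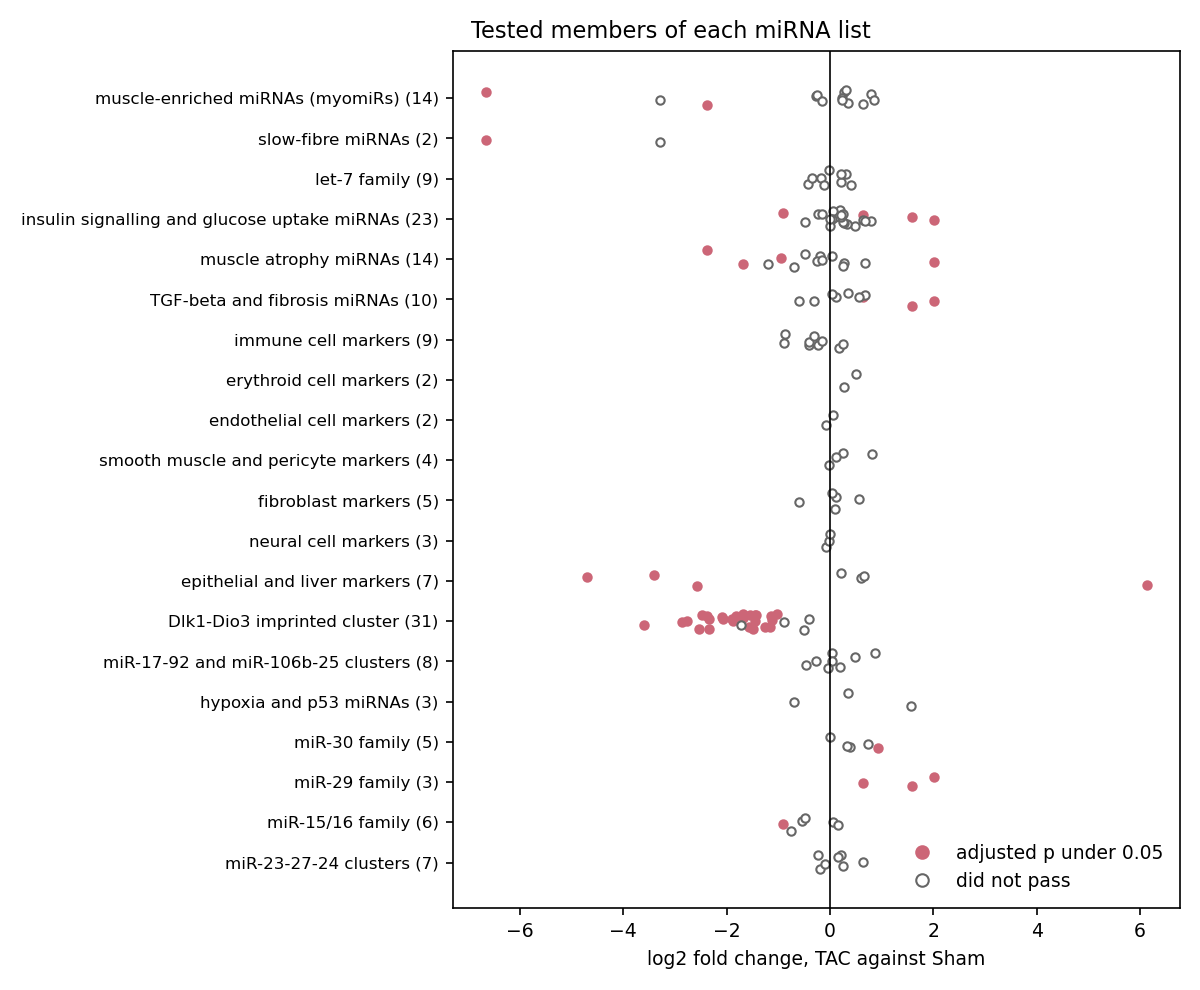
Log2 fold change of TAC against Sham for each tested member of the miRNA lists, with the number tested in parentheses, filled where the adjusted p was under 0.05. The Dlk1-Dio3 list lies below 0 in all 31 members, and the signs of members near 0 depended on the scaling.

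Transcripts typical of other organs differed between the groups. In TAC, miR-122-5p had 424, 1989 and 72.5 CPM, against 14.4, 16.4 and 2.81 CPM in Sham (log2 fold change 6.13, SE 1.27, adjusted p = 0.0157, 4.46 without TAC 2). The call was lost without Sham 1 or Sham 2 (adjusted p = 0.055 and 0.0567). Its passenger strand miR-122-3p also rose (1.57, SE 0.35). That strand had 9.75, 7.83 and 10.9 CPM in TAC 1, 2 and 3, lowest where miR-122-5p was highest. Across the TAC libraries the strands therefore did not move in proportion. In Sham, miR-429-3p had 107 UMIs against 3 in TAC, a scaled ratio of 31.4 (95% counting interval 10.5 to 154.5). The other 2 were miR-200a-3p (-3.40, SE 0.69) and miR-200b-3p (-2.56, SE 0.75). Fragments of 7 kidney mRNAs summed to 276 UMIs in Sham and 7 in TAC.

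**Figure D4:**
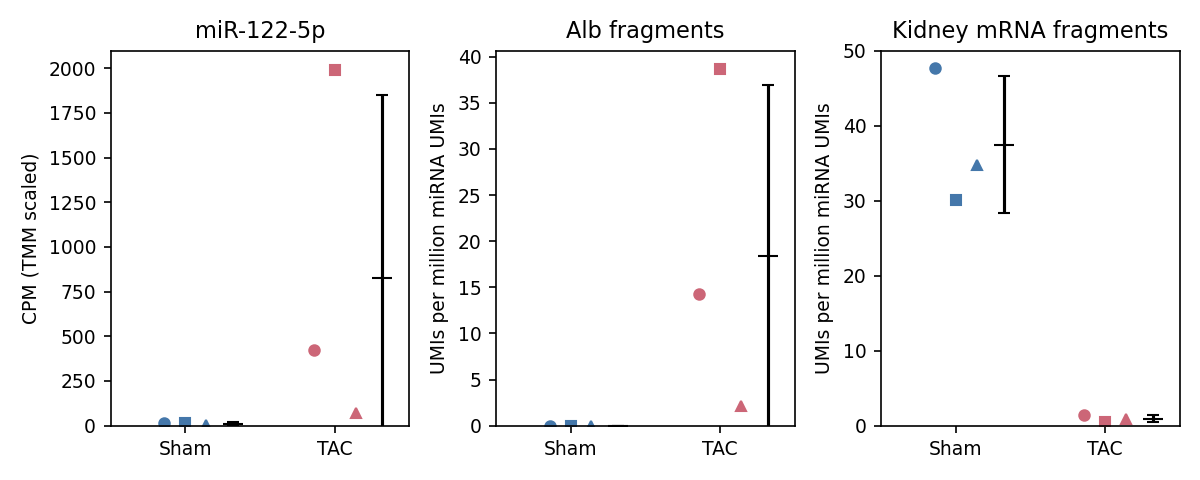
CPM of miR-122-5p (left), and UMIs per 1000000 miRNA UMIs of fragments of the liver mRNA Alb (middle) and of 7 kidney mRNAs together (right), per library with the mean and SD (cut at 0, n = 3). Symbols mark replicates 1 (circle), 2 (square) and 3 (triangle), and the kidney fragments number 164, 71 and 41 UMIs in Sham and 4, 1 and 2 in TAC.

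Besides these, the miRNAs with the smallest p among those that rose were of low or moderate abundance. They were miR-1843a-5p (113 ± 9.87 to 290 ± 53.8 CPM, log2 fold change 1.36), miR-1981-3p (1.49), miR-1968-3p (1.82), miR-1191a (1.29) and miR-1843b-5p (1.10). The last was miR-133c (1.75), with a mean of 1.68 CPM in Sham, whose sequence is close to that of miR-133a. Without Sham 1, miR-1981-3p (adjusted p = 0.0525), miR-1191a (0.0525), miR-1843b-5p (0.0683), miR-122-3p (0.0926) and miR-133c (0.0877) did not pass, and without Sham 2 neither did miR-1968-3p (0.0507). Without Sham 2, TAC 1 or TAC 2 the calls of miR-1191a, miR-1843b-5p and miR-133c were lost (adjusted p from 0.0566 to 0.097), and miR-122-3p was lost without TAC 1 (0.075) or TAC 2 (0.0649). The call of miR-133c was also lost with DESeq2 (0.0531). Of the most abundant miRNAs, miR-26a-5p rose from 29390 ± 396 to 43240 ± 5092 CPM (0.56, SE 0.15, adjusted p = 0.0345). This call was lost with library sizes only (0.27, adjusted p = 0.236) and without any 1 library other than Sham 3 (adjusted p from 0.0649 to 0.133). The log2 fold changes of miR-378a-3p (0.20, adjusted p = 0.392) and miR-126a-3p (0.07, adjusted p = 0.781) did not pass and turned negative with library sizes only.

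The other RNA classes give a by-product view of the same libraries, and 23 of 1813 tested features passed, 15 higher and 8 lower in TAC. The counts were 10 of 238 tRNAs, 4 of 49 mRNAs, 7 of 245 other RNAs, 2 of 1244 unannotated sequences and 0 of 37 piRNAs by edgeR. Of 1832 listed unannotated sequences, 1147 start in an annotated miRNA hairpin on the same strand, so this class is not separate from the miRNAs. Among piRNAs 3 had an unadjusted p under 0.05, DESeq2 called 0 and edgeR with the replicate block 1. DESeq2 called 74 features over all these classes, 52 of them unannotated sequences, where edgeR called 2. The replicate block called 211 features over all these classes. Leaving out TAC 1 gave 13, and leaving out Sham 2, Sham 3 or TAC 3 gave 60, 88 or 49.

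Among tRNAs, fragments of tRNA-Phe-GAA-1-5 (log2 fold change 2.07, SE 0.32), tRNA-Phe-GAA-1-1 (1.88) and tRNA-Gly-CCC-1-2 (1.83) rose. Fragments of tRNA-Glu-CTC-1-8 (-2.21, SE 0.54), tRNA-Glu-CTC-1-4 (-1.48) and tRNA-Asp-GTC-4-1 (-1.29) fell. Both tRNA-Glu-CTC values rest largely on Sham 3, without which they were -1.24 (adjusted p = 0.128) and -0.765 (adjusted p = 0.21), and the groups overlapped for tRNA-Glu-CTC-1-8. Both calls were also lost without TAC 1 or TAC 2 (adjusted p from 0.106 to 0.265), and that of tRNA-Asp-GTC-4-1 without any 1 library other than Sham 1 (adjusted p from 0.0646 to 0.29). Among mRNA fragments, those of Kcnj11, a subunit of the ATP-sensitive potassium channel (chromosome 7, 46098873 to 46100764), rose with a log2 fold change of 1.44 (SE 0.37, adjusted p = 0.00261). Fragments of Rtl1 fell (-1.39, SE 0.36, adjusted p = 0.00261, and 0.0999 without Sham 2 and 0.0749 without TAC 3). Rtl1 is on the minus strand at chromosome 12, 109589193 to 109600330, opposite miRNAs of the Dlk1-Dio3 cluster, so reads of the 2 strands cannot be told apart here. The kidney endocytic receptor Lrp2 had 57 UMIs in Sham and 1 in TAC, a scaled ratio of 40.6 (95% counting interval 6.996 to 1631). The fourth, a transcript with no match in the annotation, ENSMUST00000184423, also fell (-1.69, SE 0.48), with an adjusted p of 0.0502 without Sham 1 and of 0.344 without Sham 2.

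Among other RNAs, the antisense RNA A230083N12Rik (2.26, SE 0.30) and the long noncoding RNA Gm26730 (2.18, SE 0.31) rose. Gm26870, on chromosome 9 from 3000282 to 3018084, had 0 UMIs in Sham and 69 in TAC, at least 25.9-fold higher against a floor of 3 UMIs over the Sham group. The unannotated sequences that fell included a sequence within the miR-382 hairpin of the Dlk1-Dio3 region, starting at chromosome 12, 109733817 (-2.45, SE 0.33). The other, at chromosome 1, 171045019, had 76 UMIs in Sham and 3 in TAC, a scaled ratio of 27.5 (95% counting interval 9.06 to 136). Both calls were lost without Sham 1, TAC 1 or TAC 2.

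Libraries of the groups also differed in makeup. Reads assigned to miRNA were 74.1% ± 1.53 of all reads in Sham and 78.3% ± 0.881 in TAC (SD, n = 3), a difference of 4.19 percentage points, with every TAC library above every Sham library. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, and 0.24 after adjustment over 12 read categories. The share of tRNA reads was 1.96% ± 0.15 in Sham and 1.28% ± 0.0892 in TAC (exact permutation p = 0.1, adjusted 0.24).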

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

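All tests in this part were chosen only after the results were seen. Rows of the mRNA table that the count filter left out of the comparisons held fragments of liver transcripts above the level in the Sham libraries. Fragments of Alb, the mRNA of serum albumin, numbered 129 UMIs over the TAC libraries (41, 83 and 5) and 0 over the Sham libraries, at least 41.03-fold higher per miRNA UMI and at least 60.4-fold per TMM-scaled mRNA UMI, against a floor of 3 UMIs over the Sham group. Alb was higher in every TAC library (exact permutation p = 0.1, the smallest possible with 3 against 3). Fragments of Cyp2e1, a liver cytochrome, numbered 24 in TAC (6, 17 and 1) and 1 in Sham (in Sham 2). Its rates per miRNA UMI also did not overlap (exact permutation p = 0.1), but TAC 3 and Sham 2 tie at 1 UMI and are parted by library size alone (0.436 and 0.424 per 1000000).

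The pattern is RNA of other organs that differs between the groups: miR-122-5p and some liver mRNA fragments in TAC, and kidney mRNA fragments in Sham. Of 17 liver mRNAs in a marker list 5 were listed, and Alb was higher in every TAC library, while Cyp2e1 tied in counts as above. The others overlapped: Apob (10 UMIs in Sham, 83 in TAC, of which 1 in TAC 3; exact permutation p = 0.4), Fgg (46 and 53, p = 1) and C3 (18 and 36, p = 0.6). All 5 together overlapped as well, with 15.3 per 1000000 miRNA UMIs in TAC 3 and 17.8 in Sham 3 (exact permutation p = 0.2). UMIs of miR-122-5p per liver fragment spanned 1.38-fold over TAC 1, 2 and 3 with the Sham means subtracted, 1.85-fold per Alb fragment, and 5.02-fold with nothing subtracted (11.3, 20.96 and 4.17), beyond the 3-fold that was taken as 1 source. Of the 35 UMIs of these 5 liver mRNAs in TAC 3, 25 were of Fgg, which overlapped between the groups. The form with nothing subtracted therefore leans on Fgg in TAC 3. Liver RNA in the TAC libraries is a candidate source of both signals. It cannot be told apart from others, since the forms of this ratio disagree, at least in part through Fgg, and TAC 3 holds 5 Alb UMIs.

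Of 14 kidney mRNAs 7 were listed, led by Gpx3 (89 UMIs in Sham, 4 in TAC), Lrp2 (57 and 1) and Umod (41 and 0), and 7 had a higher rate in every Sham library, 1 of them, Kap, with 1 UMI each in Sham 3 and TAC 3, which may reflect kidney RNA in Sham. That marker list was drawn up after the fragments had been seen, so its count could hardly have come out otherwise, and the miRNA readouts did not all go the same way. The summed UMIs of miR-200a-3p, miR-200b-3p and miR-429-3p per kidney fragment were 1.44, 2.20 and 0.659 in Sham 1, 2 and 3, a span of 3.34-fold, and 6 kidney miRNAs summed to 336 CPM in Sham and 413 CPM in TAC. That sum was 434, 522 and 282 CPM in TAC 1, 2 and 3, in the same order as miR-122-5p. Liver RNA may therefore add to it in TAC, so the higher TAC sum does not count against kidney RNA in Sham. Tissue carried over at dissection, cross-talk between pooled libraries, RNA delivered by blood and an effect of TAC on it stay open and were not tested apart. No marker of heart (10), fat (7) or red blood cells (5) was among the listed mRNAs.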

How the results depend on the processing

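Leaving out both libraries numbered 3, and the Dlk1-Dio3 list drawn by position, were chosen only after the results were seen. All 23 named miRNAs that passed kept their direction under every alternative that tested them, and 12 of them passed under all of these. Among the 23, miR-323-3p, miR-122-3p and miR-133c were tested in 17 of 18 alternatives. Of 14 named miRNAs that did not pass, 3 passed under some alternative (miR-133b-3p, miR-133a-3p and miR-499-5p) and 8 changed sign. The number of miRNAs past the threshold, 71, became 111 with the replicate block and 129 without both libraries numbered 3, and ranged from 17 to 73 over the fits without 1 library. It stayed between 52 and 96 under the others, and 17 calls without Sham 1 were all among the 71. The number of lists, 2, became 1 with an estimated inter-gene correlation, 3 with fry, which added the muscle atrophy list, 3 with the list by position added, and 1 without both libraries numbered 3, and ranged from 1 to 4 over the fits without 1 library. The number of other features, 23, became 43 without a filter, 74 with DESeq2, 211 with the replicate block and 136 without both libraries numbered 3, and ranged from 13 to 88 without 1 library. Besides the counts and the 3 miRNAs named above, the replicate block changed no call of a named miRNA or a list. Fewer libraries leave fewer degrees of freedom for the tests, and the cause of the other changes was not tested. The difference in the share of miRNA reads kept its sign everywhere.

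With library sizes only, log2 fold changes that changed sign were miR-1a-3p (-0.0019), miR-378a-3p (-0.072), miR-486b-3p (-0.069), miR-126a-3p (-0.20) and miR-1a-2-5p (-0.00018), and with library sizes over all RNA classes miR-378a-3p (-0.038), miR-486b-3p (-0.037) and miR-126a-3p (-0.17). These follow from the shifts of -0.28 and -0.24 in the median. Without both libraries numbered 3, miR-126a-3p was at -0.057. Without Sham 3, miR-486a-3p (0.051), miR-486a-5p (0.20), miR-486b-5p (0.28) and miR-1a-2-5p (-0.12) changed sign, as did miR-486b-5p (0.030) and miR-1a-2-5p (-0.38) without TAC 1 and miR-486b-3p (-0.21) without TAC 3. Over the fits without 1 library, the other ends of the ranges were -0.63 for miR-486a-3p, -0.505 for miR-486a-5p and -0.397 for miR-486b-5p (without TAC 3), 0.556 for miR-486b-3p (without Sham 3) and 1.11 for miR-1a-2-5p (without Sham 2). At this depth and with 3 libraries per group, simulated 2-fold changes were recovered in 40.8% of cases, so a miRNA that did not pass is not shown to be unchanged.

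The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The split into Sham and TAC called 71 miRNAs and the highest other split 0, and for other features the values were 23 and 1. In both, 1 split gave as many. Every other split mixes Sham and TAC on both sides, so a difference between the groups adds to the spread within each side. Low feature counts there would follow from any such difference, whatever its cause. For lists the values were 2 and 3, and 4 of the 10 splits called as many lists as the real one. Every other split called at least 1 list, and each of the 3 others that part every pair of numbers called 1. The number of lists therefore does not set the real split apart. Each other split holds Sham and TAC in uneven numbers. Its list calls may carry part of that difference or come from the preset correlation, which was not tested apart.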

Other observations

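The groupings by position and the tests of explanations in this part were chosen only after the results were seen, as were the miRNAs and transcripts named outside the naming rule. Of 19 groups of neighbouring miRNAs outside the chromosome 12 cluster, 14 had no member past the edgeR threshold and 3 had most or all members past it in 1 direction; whether neighbours moved together was not tested. One of the 3 is the miR-200a, miR-200b and miR-429 locus. In a cluster on chromosome X (7237683 to 7248497, minus strand) 4 of 6 tested miRNAs fell, namely miR-532-5p, miR-532-3p, miR-500-3p and miR-362-3p, and all 6 were below 0, with a median log2 fold change of -1.38. At the miR-29b-2 and miR-29c locus on chromosome 1 (195037040 to 195037634) 3 of 3 tested miRNAs rose, and fragments of the annotated host transcript A330023F24Rik rose as well (log2 fold change 1.23, adjusted p = 0.0316 by edgeR). By contrast, miR-206-3p fell and miR-133b-3p had a log2 fold change of 0.80 within the same annotated gene. The miR-133b-3p value may include reads of the near-identical miR-133a-3p, so this contrast may come from how reads were assigned. Other changes were miR-10b-5p, which fell from 6552 to 2915 CPM (-1.17), and miR-483-5p, from the Igf2 gene, which fell (-2.66).

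The fall of the Dlk1-Dio3 miRNAs was set against 3 technical explanations. Kidney RNA in the Sham libraries would bring kidney miRNAs with it, but 6 of these summed to 336 CPM in Sham and 413 CPM in TAC, while the cluster list lost 2550 CPM. These 6 were chosen after the values were seen. Their sum speaks to kidney RNA only as far as they stand for that organ, and does not rule it out. The TAC sum may hold liver RNA, so only the Sham level bears on this comparison. A scaling factor moves all miRNAs of a library alike, but the gap between the median log2 CPM of the list and that of the other miRNAs was lower in every TAC library, by -1.46 on average (pooled SD 0.38, exact permutation p = 0.1, the smallest possible), which argues against scaling as the whole cause. With upper-quartile factors, which shift the median up by 0.077, 25 of 31 list members fell, and 30 of 32 fell without both libraries numbered 3. Besides kidney RNA, an effect of TAC stays open, which was not tested apart from the groups. So does any difference in the muscle or the part of it taken, which may move the cluster too. An effect of the order in which the libraries were numbered, which follows the groups, also stays open.

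The lower miR-208b-3p, miR-499-5p and miR-206-3p in TAC were set against depth: at the Sham mean the TAC libraries together would have held 240.5, 153 and 82170 UMIs of these miRNAs and held 2, 15 and 15260, which argues against counting depth. Set against fewer fast oxidative (IIa) fibres, the share of Myh2 among Myh1, Myh2 and Myh4 fragments (156 to 252 UMIs per library) was 20.2%, 9.44% and 20.2% in Sham and 7.23%, 6.41% and 9.79% in TAC, a difference of -8.83 percentage points (exact permutation p = 0.2), lower in 3 of 3 pairs of same-numbered libraries (exact paired p = 0.25, the smallest possible). Myh2 was lower in every TAC library relative to miRNA UMIs and to all mRNA fragment UMIs, while mRNA reads as a whole were 0.493% of reads in Sham and 0.346% in TAC, and neither Myh2 nor Myh1 passed in the mRNA test. The log2 fold change of miR-208b-3p lay beyond that of Myh2 per miRNA UMI (-1.56, SE 0.57) by -5.09 (SE 1.19), which argues against IIa fibres as its whole cause if it follows their number, while the gaps for miR-499-5p (-1.74, SE 1.25) and miR-206-3p (-0.81, SE 0.85) are under 2 SE and leave fewer IIa fibres a candidate explanation for these. The miRNA values were TMM scaled and Myh2 per miRNA UMI was not. With library sizes only, the median log2 fold change of miRNAs shifted by -0.28, so these gaps would be wider on 1 scale. Slow fibres, whose myosin Myh7 is not among the listed mRNAs, an effect of TAC and a different piece of muscle stay open and would look alike in these data.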
